A study of Mus musculus with 10 samples.

How the data were processed

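RNA was measured in B220+ cells sorted from pre-B colonies (CFU-PreB, colony-forming units of B cell precursors grown in methylcellulose with the cytokine mix of the medium) after 7 days of culture. The bone marrow came from 5 Hspa9+/+ mice, littermates per the labels and here called wild type, and 5 Hspa9+/- mice, here called heterozygous, each cultured independently per the series design. Hspa9 encodes mortalin, a chaperone of the heat shock protein family in the mitochondrial matrix. Per the labels' protocols, cells were sorted into TRIzol, cDNA was amplified with a NuGEN kit and each sample was hybridised to a Mouse Gene 1.0 ST array. The deposited values are gene-level RMA expression on the log2 scale, made by the authors with Affymetrix Expression Console per the labels. Versions, genome build and annotation of that step were not given in the sources used here. RMA corrects the background, normalizes arrays to a shared distribution and summarises the probes of a probe set. A shift of most genes in one direction would therefore be largely removed from these values.

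The table holds 35556 probe sets on 10 arrays, each column matched to its sample by the labels. Array medians ran from 5.38 to 5.49 on the log2 scale. The number of arrays limits the precision. Probe sets were named through the platform annotation: 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Symbols were checked through the Entrez identifier against the RefSeq gene table of assembly GRCm38.p6, where 21698 matched. That table was used only for names and for which genes neighbour each other. An older symbol in a list was matched to a current one only if it is not itself the current symbol of another gene. This matching rule was corrected after the list results had first been seen, which took 1 wrongly matched gene out of the glycolysis list. Probe sets with 1 symbol were kept, with 1 row per symbol (19938 symbols, 999 with several probe sets), taking the probe set of highest mean over all arrays. Rows with a mean at or below the 25th percentile (4.52 log2) were left out, which left 14953 genes.

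Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as heterozygous minus wild type, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors (SE) are limma's moderated ones. Single values, such as Hspa9 or the mean of a list, were also compared by a two-sided exact permutation test over all 252 splits of the 10 arrays. The smallest p that test can give is 0.0079.

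Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 34 lists, and a list needed 3 measured members. A camera call compares a list with the other genes. Lists were also tested by camera with an estimated correlation, by fry and by exact permutation of the list mean. The gene lists were IL-7 and STAT5 induced genes, IL-7 receptor pathway components, pre-BCR and BCR signalling, small pre-B differentiation, pro-B and early progenitor genes, V(D)J recombination and end joining, DNA replication and G1/S, G2/M and mitosis, mitochondrial chaperones import and proteases, cytosolic heat shock response, endoplasmic reticulum unfolded protein response, integrated stress response (ATF4), p53 target genes, apoptosis regulators, oxidative phosphorylation, iron-sulfur cluster and iron handling, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, glycolysis, cholesterol synthesis, interferon response, immediate early genes and genes next to Hspa9. The cell type lists were B lineage, immature and mature B cell, plasma cell, neutrophil lineage, monocyte and macrophage, erythroid, megakaryocyte, mast cell and basophil, plasmacytoid dendritic cell, T cell and NK cell, and stroma. Some genes stand in more than 1 list.

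The named genes were chosen by a rule: Hspa9, the sort marker gene Ptprc, up to 10 genes per direction past the threshold or else the 5 of smallest p in that direction, and per list up to 4 members past the test adjusted over the list alone or else the 2 of smallest p. Predicted genes, olfactory and vomeronasal receptor genes, small RNA genes and receptor segments were not named. Any other gene that is named was chosen after its values were seen. The groups, tests, lists, naming rule and alternative settings were fixed before the data were examined.

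The alternative settings were other filters on dim probe sets, every probe set as its own row, other normalizations between arrays, a trended and robust variance, array weights, the replicate number as a block, mouse sex as a covariate, markers of other cell types as a covariate, other thresholds and set tests, and each array left out in turn. Other-cell markers as a covariate stand for the mean of the neutrophil lineage, monocyte and macrophage, erythroid and megakaryocyte lists. The plasma cell, mast cell and basophil, plasmacytoid dendritic cell, T cell and NK cell, and stroma lists are not in it. Macrophage markers as the covariate, and leaving out together the pair of arrays with the highest macrophage markers, were added after seeing the data.

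The model was tested on simulated data for the same comparison, 14953 genes with the measured means and spreads, of which 200 were changed, 50 of each size. It recovered 30% of changes of 0.5 log2, 82% of changes of 1, 90% of changes of 1.5 and 96% of changes of 2, with 6 unchanged genes called. The simulated genes were independent, which the genes of these arrays are not.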

Results

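B220+ cells from day 7 pre-B colonies of 5 wild type and 5 heterozygous mice were profiled on 10 arrays, 1 per mouse. The comparison asks how loss of 1 Hspa9 allele alters gene expression in B cell precursors grown in colonies. Values are RMA log2 units and differences are heterozygous minus wild type, with n = 5 per genotype except where arrays are said to be left out.

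Hspa9 itself was lower in heterozygous cells. Its mean was 9.92 in wild type and 9.18 in heterozygous arrays, a difference of -0.73 (SE 0.185), which places heterozygous cells at 60.3% of the wild type level (95% interval 45.4 to 80.0%). By array, the wild type values were 9.49, 9.57, 10.36, 10.17 and 9.99, and the heterozygous values were 9.52, 8.92, 9.30, 9.21 and 8.97. Heterozygous 1 therefore lay above wild type 1. The exact permutation test of this single gene gave p = 0.0159. Among all genes the limma adjusted p was 0.345, so Hspa9 did not pass there, and with array weights the difference was -0.79 with an adjusted p of 0.0381. 1 probe set measures Hspa9, and whether it lies in the disrupted part of the gene is not known here.

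**Figure D1:**
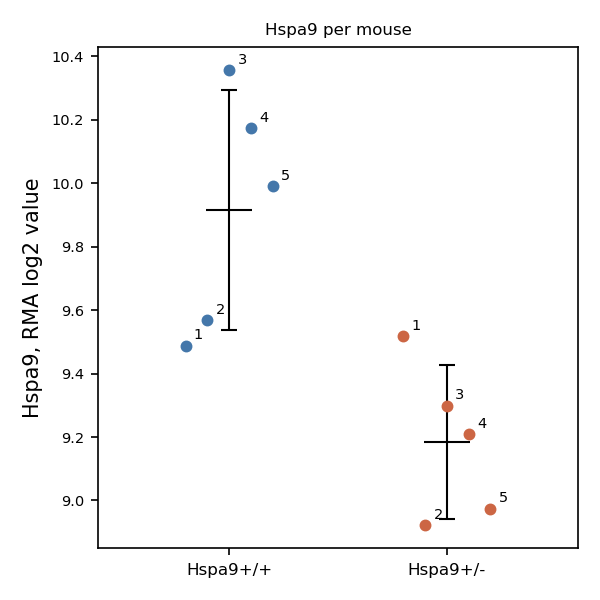
Hspa9 expression per mouse (vertical axis, RMA log2 value) by genotype (horizontal axis), where points are mice with their replicate number and bars are the mean and SD of 5 mice. The heterozygous mice lie between 8.92 and 9.52 and the wild type mice between 9.49 and 10.36.

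The genes listed beside Hspa9 did not shift as a group. Their mean difference was -0.06 over 17 measured members (camera adjusted p = 0.384), 0 passed over all genes and 1 fell when adjusted over the list alone. Without 1 array the mean ran from -0.11 (without wild type 1) to -0.018 (without wild type 3). That gene was Paip2, a regulator of poly(A)-binding protein, at -0.43 (SE 0.0862). Myot, although in the list, lies 149 genes away from Hspa9 in the gene table.

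No single gene passed the limma threshold over all 14953 genes. At an unadjusted p under 0.05 there were 1650 genes, where 5% by chance would be 748. Of the 1650, 1015 were higher and 635 lower in heterozygous cells. The median difference over all genes was 0.058, against 0.018 for rows above the median row and 0.014 with quantile normalization of the rows kept. The larger number of higher genes is to be read against that shift. The groups did not overlap for 341 genes, 220 higher and 121 lower, against 0.794% or 119 genes by chance. Genes are not independent and this count was not compared with other splits of the arrays, so chance is not excluded for it. The smallest adjusted p, 0.0795, belonged to Bcar3 at -0.83 (SE 0.107), an adaptor of integrin signalling, and to Lmo4 at -0.92 (SE 0.121), a LIM-domain transcriptional cofactor. The next lower genes were Card6 at -1.14, Fcrla, an Fc receptor-like protein of B cells, at -0.94 and Tmem243 at -1.27. The higher genes of smallest p were Nol4l at 0.77, the interferon-inducible membrane protein Ifitm1 at 1.02, the phosphatidate phosphatase Lpin3 at 0.47, Rgcc at 0.58 and Myoz1 at 0.46. In all 10 of these genes the genotypes did not overlap, and none passed adjustment. Myoz1 and Lpin3 were dim, with wild type means of 4.52 and 4.90, close to the filter's cutoff of 4.52. The sort marker gene Ptprc, which encodes B220, was at -0.68 (SE 0.345, adjusted p = 0.490), and at -0.40 without heterozygous 5. The count of 0 was 137 with array weights, 22 without wild type 1, 3 without heterozygous 2 and 26 without both of these arrays, the last chosen after seeing the data.

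By gene list, genes of later B cell stages had lower means, and genes of glycolysis and of T, NK and plasmacytoid dendritic cells had higher means in heterozygous cells. Camera called 11 of the 34 lists, 5 higher and 6 lower. None of these calls held with an estimated correlation (7 lists at an unadjusted p under 0.05, smallest adjusted p = 0.188), fry called 5, and exact permutation of the list mean called 0 (8 lists at an unadjusted p under 0.05, smallest adjusted p = 0.0675). For 4 lists the exact permutation p was the smallest possible, 0.0079, so their adjusted p of 0.0675 reflects the resolution of that test. Of 100 splits of the arrays, 20 gave 11 camera calls or more, the real one included. In 16 of these, wild type 1 and heterozygous 2, the arrays highest in macrophage genes, fell in one group, and of the 54 splits that part them, as the real one does, 4 gave as many. Apart from the real one, those 4 each exchange a single pair of arrays between the genotypes. Over all genes, 0 members of any list passed, so member counts below are adjusted over the list alone.

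Immature and mature B cell genes fell by 0.67 on average, from 8.67 ± 0.398 to 7.99 ± 0.132 (SD), and every heterozygous array lay below every wild type array. The camera adjusted p was 1.6e-10 and the adjusted p = 0.188 with an estimated correlation. Of 14 measured members 7 fell and 7 did not pass when adjusted over the list alone. They included S1pr1, the sphingosine phosphate receptor used in egress, at -0.95 (SE 0.149), the complement regulator Cd55 at -1.82 (SE 0.291), Ms4a1, which encodes CD20, at -1.57 (SE 0.313), and Tnfrsf13c, the BAFF receptor, at -0.81 (SE 0.186).

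Small pre-B differentiation genes fell by 0.42 (camera adjusted p = 2.9e-09). Here too every heterozygous array lay below every wild type array, and the adjusted p = 0.188 with an estimated correlation. Of 19 measured members 8 fell and 0 rose when adjusted over the list alone, among them the adhesion receptor Cd2 at -1.24 (SE 0.242), the invariant chain Cd74 at -0.74 (SE 0.150), the chemokine receptor Cxcr4 at -0.57 (SE 0.128) and the cyclin-dependent kinase inhibitor Cdkn1b at -0.60 (SE 0.147).

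The B lineage list fell by 0.32 (camera adjusted p = 0.000359, adjusted p = 0.235 with an estimated correlation). Adjusted over the list alone 2 of 14 members fell, the guanine nucleotide exchange factor Ralgps2 at -1.35 (SE 0.279) and the inhibitory receptor Cd22 at -0.98 (SE 0.230), while the other 12 did not pass. V(D)J recombination and end joining genes fell by 0.17 (camera adjusted p = 0.00247, adjusted p = 0.235 with an estimated correlation). The difference was -0.11 without heterozygous 5 (adjusted p = 0.00554) and -0.11 with macrophage markers as covariate (adjusted p = 0.0417) or other-cell markers (adjusted p = 0.0445). Adjusted over the list alone its members moved apart: the recombinase genes Rag1 at -0.79 (SE 0.231) and Rag2 at -0.59 (SE 0.177, -0.39 with array weights) fell, and Dntt, the terminal transferase that adds bases at junctions and is most active in pro-B cells, rose by 1.49 (SE 0.443). Pre-BCR and BCR signalling genes fell by 0.14 (camera adjusted p = 0.0434, adjusted p = 0.514 with an estimated correlation), with 1 of 20 lower when adjusted over the list alone, the scaffold Bank1 at -1.32 (SE 0.228). That call held in 11 of 26 alternatives and was lost in 4 of the 10 fits without 1 array, with adjusted p of 0.0687 without wild type 1, 0.170 without wild type 2, 0.107 without heterozygous 1 and 0.146 without heterozygous 2. It was also lost with array weights (-0.088, adjusted p = 0.249), quantile normalization (adjusted p = 0.231), cyclic loess (0.0896), and macrophage markers (0.0794) or other-cell markers (0.0936) as covariate, among others.

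Pro-B and early progenitor genes, which mark the stage before, had a mean difference of 0.25 and missed the threshold (camera adjusted p = 0.0524, adjusted p = 0.521 with an estimated correlation), with 0 of 17 members past the test adjusted over the list alone. The list passed in 13 of 26 alternatives, as with array weights (0.37, adjusted p = 0.00297). Dntt and the surrogate light chain gene Vpreb2, at 0.51 (SE 0.162), had the smallest p of its members. Plasma cell genes did not shift as a list (0.03, camera adjusted p = 0.812; 0.00016 to 0.066 without 1 array). Adjusted over the list alone, the transcription factor Prdm1 fell by 0.73 (SE 0.176) and Xbp1, a regulator of the secretory programme, rose by 0.41 (SE 0.129).

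**Figure D2:**
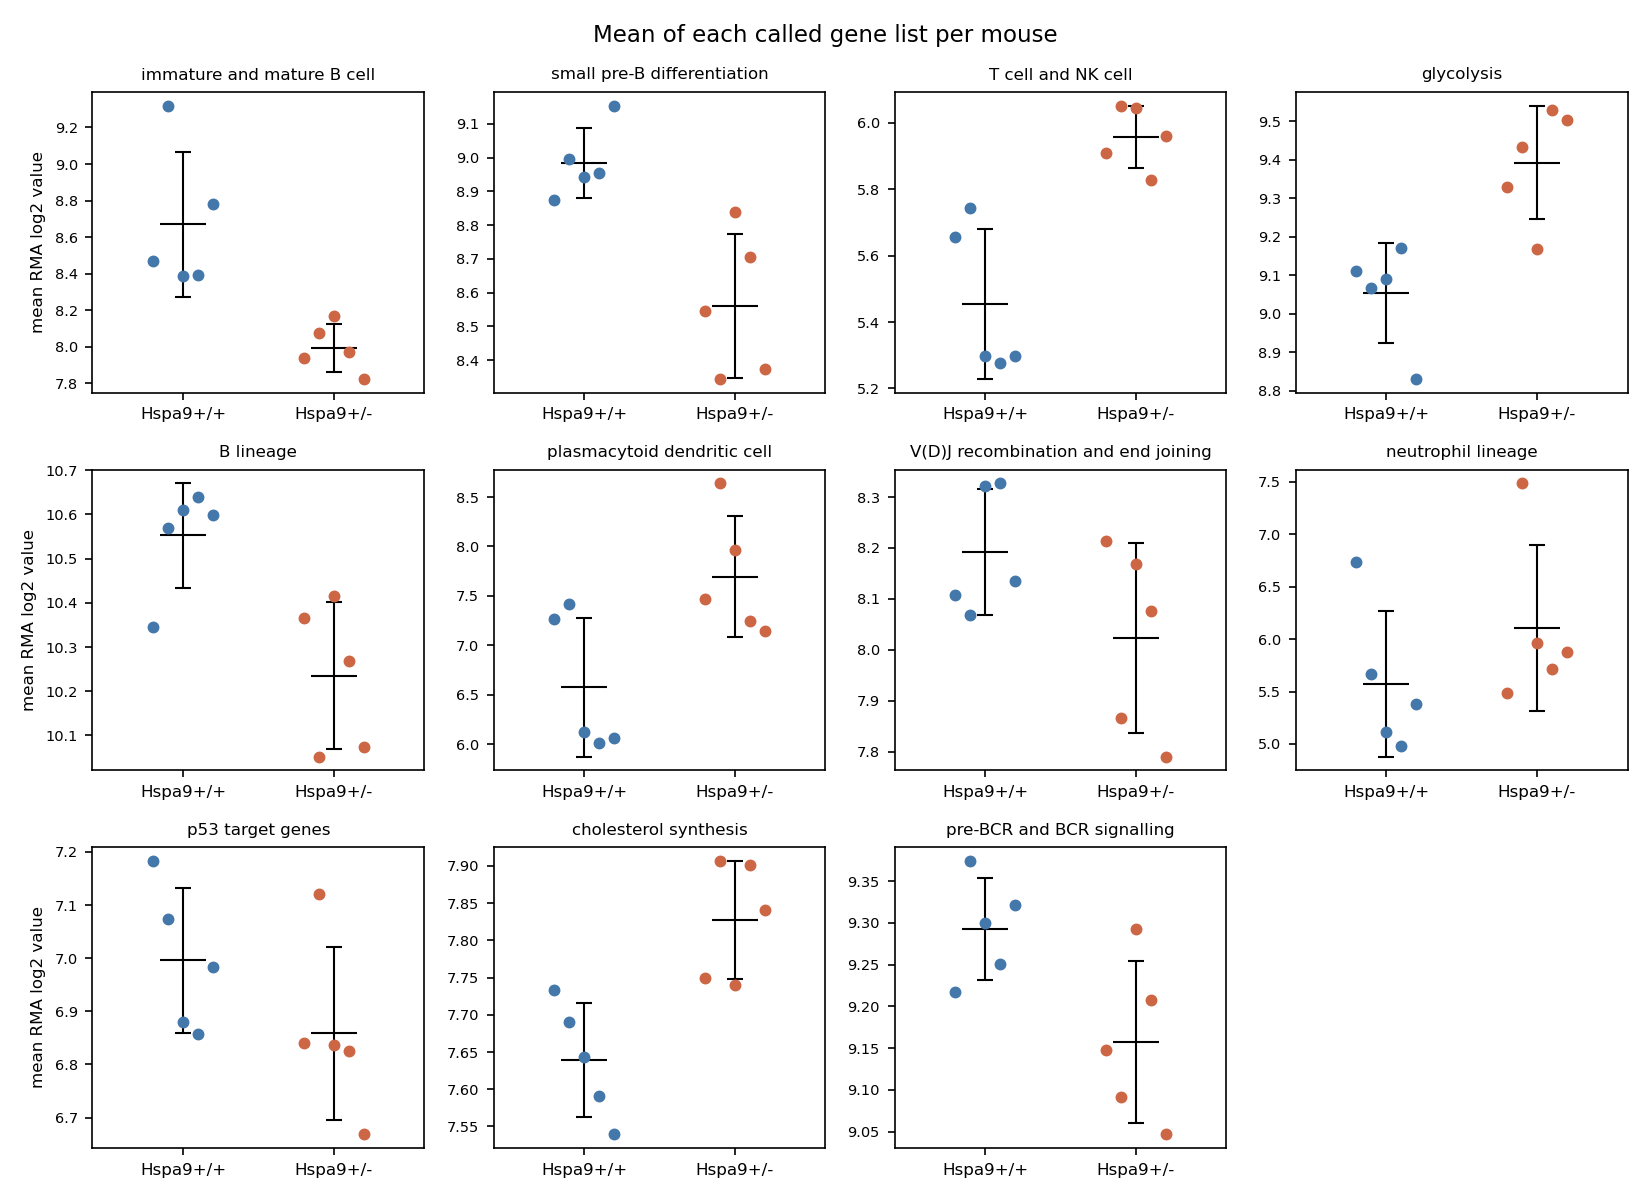
Mean RMA log2 value over the measured members (vertical axes, each panel on its own scale that does not start at 0) of the 11 lists called by camera, by genotype (horizontal axes), where points are mice and bars are the mean and SD of 5 mice. The genotypes do not overlap for immature and mature B cell, small pre-B differentiation, T cell and NK cell, and cholesterol synthesis genes.

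Of the marker lists of other cell types, camera called T cell and NK cell, plasmacytoid dendritic cell and neutrophil genes higher in heterozygous samples. T cell and NK cell genes rose by 0.50 (camera adjusted p = 0.000176, adjusted p = 0.188 with an estimated correlation). Of 9 measured members 5 rose when adjusted over the list alone, among them Nkg7 of cytotoxic granules at 0.68 (SE 0.149), Thy1 at 0.71 (SE 0.211), Cd3e of the T cell receptor complex at 0.38 (SE 0.119) and the interleukin 2 receptor chain Il2rb at 0.39 (SE 0.125). Thy1 had a wild type mean of 8.29. Nkg7, Cd3e and Il2rb were dim, at 4.97, 5.02 and 4.54, close to the filter's cutoff of 4.52. Over the 3 members above the median row the difference was 0.87. Plasmacytoid dendritic cell genes rose by 1.12 (camera adjusted p = 0.00105, adjusted p = 0.310 with an estimated correlation), and these cells carry B220 themselves. Adjusted over the list alone 4 of 5 rose, Siglech by 1.63 (SE 0.477), Bst2 by 0.72 (SE 0.246, 0.48 with macrophage markers as covariate), Pacsin1 by 0.46 (SE 0.159) and the chemokine receptor Ccr9 by 1.72 (SE 0.598). Neutrophil lineage genes rose by 0.53 as a list (camera adjusted p = 0.0221, adjusted p = 0.798 with an estimated correlation), with 0 of 15 members past the test adjusted over the list alone, Mmp9 at 0.24 and Ctsg at 0.38. Without heterozygous 2 Mmp9 was at 0.15 and Ctsg at 0.18, the neutrophil difference was 0.18 and the call was lost (adjusted p = 0.568), and it was also lost without wild type 2 (0.0541), wild type 3 (0.0612) or wild type 5 (0.0585), while without wild type 1 the difference was 0.82. With macrophage markers as covariate it was 0.08 (adjusted p = 0.733).

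Monocyte and macrophage genes varied most between arrays. Their mean was 8.98, 7.55, 5.88, 5.73 and 5.85 in the wild type arrays and 7.19, 9.44, 7.15, 6.99 and 7.25 in the heterozygous arrays, a difference of 0.80 that did not pass (camera adjusted p = 0.0513, adjusted p = 0.798 with an estimated correlation) with 0 of 16 members past the test adjusted over the list alone. The list passed in 16 of 24 alternatives but not in exact permutation of its mean (adjusted p = 0.540), and its difference ran from 0.35 to 1.35 without 1 array, the highest without wild type 1 (adjusted p = 4.1e-05). Lyz2, the macrophage lysozyme, was at 1.45 (SE 0.741) and the receptor Csf1r at 1.26 (SE 0.800), the latter at 1.90 without wild type 1 and 0.82 without heterozygous 2. The first principal component of the arrays held 52.8% of the variance and had wild type 1 and heterozygous 2 at one end. With the macrophage marker mean as a covariate, the differences were -0.72 for immature and mature B cell genes, -0.37 for small pre-B differentiation, 0.32 for glycolysis, 0.42 for T cell and NK cell genes, 0.74 for plasmacytoid dendritic cell genes and 0.08 for neutrophil genes.

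**Figure D3:**
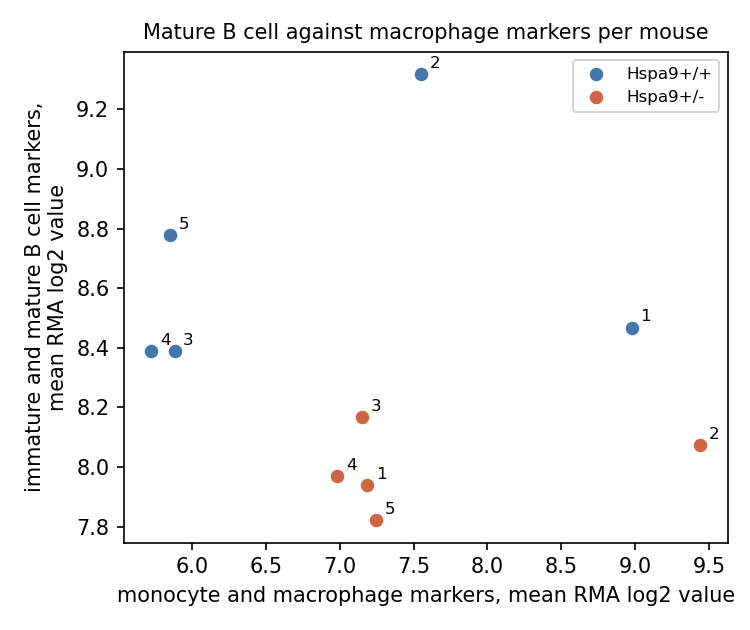
Mean RMA log2 value of immature and mature B cell genes (vertical axis) against that of monocyte and macrophage genes (horizontal axis), where each point is a mouse with its replicate number, coloured by genotype. Heterozygous mice lie lowest on the vertical axis across the range of macrophage values, from 6.99 to 9.44.

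Of the other marker lists, stroma was at 0.17 (camera adjusted p = 0.0732; Col3a1 0.29, Col1a1 0.20), megakaryocyte at 0.42 (adjusted p = 0.605; Gp9 0.11, Pf4 1.05), mast cell and basophil at 0.09 (adjusted p = 0.605; Gata2 0.19, Il4 0.10) and erythroid at 0.09 (adjusted p = 0.609; Slc4a1 0.19, Car1 0.22). None had a member past the test adjusted over the list alone. The megakaryocyte values rested on single arrays: the list was at 0.88 and Pf4 at 2.04 without wild type 1, and at 0.038 and 0.17 without heterozygous 2. Without 1 array the erythroid list ran from 0.046 to 0.14, Car1 from 0.053 to 0.38, Gp9 from 0.059 to 0.17, Gata2 from 0.12 to 0.23 and Il4 from 0.035 to 0.15. Stroma passed with the replicate block (adjusted p = 0.0357) and without wild type 5 (0.0384), heterozygous 3 (0.0451) or heterozygous 4 (0.0476).

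Among metabolic genes, glycolysis rose by 0.34 (camera adjusted p = 0.000252, adjusted p = 0.235 with an estimated correlation). Of 13 measured members 7 rose when adjusted over the list alone, among them the pyruvate kinase Pkm at 0.53 (SE 0.132), triose phosphate isomerase Tpi1 at 0.56 (SE 0.163), hexokinase Hk2 at 0.45 (SE 0.136) and the glucose transporter Slc2a1 at 0.46 (SE 0.145). Cholesterol synthesis rose by 0.19 (camera adjusted p = 0.0404, adjusted p = 0.246 with an estimated correlation), with 1 of 18 members higher when adjusted over the list alone, Dhcr7 of the last step at 0.60 (SE 0.151). That call was lost without wild type 2 (adjusted p = 0.0602), wild type 5 (0.155), heterozygous 2 (0.167) or heterozygous 4 (0.0843). It was also lost with macrophage markers (0.15, adjusted p = 0.0794) or other-cell markers (0.15, adjusted p = 0.0780) as covariate. Further losses came with array weights (adjusted p = 0.0814) or trended variance (0.0576), and without wild type 1 and heterozygous 2 (0.104). Nuclear encoded oxidative phosphorylation genes were at 0.10 (camera adjusted p = 0.131; Atp5a1 0.17, Ndufs7 0.27), mitochondrial ribosomal proteins at 0.13 (adjusted p = 0.131; Mrpl12 0.34, Mrpl2 0.29), iron-sulfur cluster and iron handling genes at 0.05 (adjusted p = 0.869; Ireb2 -0.49, Fdx1 0.23) and cytosolic ribosomal proteins at 0.02 (adjusted p = 0.765; Rps19 0.16, Rps3 0.09). These 4 lists had 0 members past the test adjusted over the list alone. Without wild type 2 or heterozygous 3 camera called oxidative phosphorylation (0.15, adjusted p = 0.0108, and 0.14, 0.0164) and mitochondrial ribosomal proteins (0.18, adjusted p = 0.0277, and 0.16, 0.0284), and both also passed with cyclic loess (adjusted p = 0.0216 and 0.0132) and quantile normalization (0.0448 and 0.00552). The lowest values of these lists without 1 array were 0.066 and 0.085. Over all 10 arrays camera with an estimated correlation gave them adjusted p of 0.818 and 0.798. Iron-sulfur genes ran from -0.0065 (without heterozygous 2) to 0.11 and cytosolic ribosomal proteins from -0.013 (without wild type 1) to 0.029 without 1 array, so neither direction held, and among their members and those of oxidative phosphorylation Ndufs7 ran from 0.17 to 0.36, Fdx1 from 0.15 to 0.30, Rps19 from 0.092 to 0.22 and Rps3 from 0.047 to 0.14.

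Of the stress lists, camera called the p53 targets. Mitochondrial chaperones, import and proteases were at 0.06 (camera adjusted p = 0.604; Timm17b 0.40, Htra2 0.30), the cytosolic heat shock response at -0.03 (adjusted p = 0.384; Fkbp4 0.40, Chordc1 -0.43), the integrated stress response at 0.21 (adjusted p = 0.194; Ddit3 -0.34, Asns 0.69) and apoptosis regulators at -0.03 (adjusted p = 0.605; Hrk 0.29, Pmaip1 -0.34), each with 0 members past the test adjusted over the list alone. Without 1 array the mitochondrial chaperones ran from 0.014 (without wild type 1) to 0.087 (without wild type 3), apoptosis regulators from -0.043 to -0.016 and the heat shock response from -0.085 to 0.021, the latter above 0 without wild type 3 or heterozygous 5. Without wild type 1, which had the highest mean of the integrated stress response, that list was at 0.35 and was called (adjusted p = 0.000493), as it was with array weights (0.27, adjusted p = 0.0174). With macrophage markers as covariate the list was at 0.084 (camera adjusted p = 0.901). With an estimated correlation it was not called, over all 10 arrays (adjusted p = 0.818) or without wild type 1 and heterozygous 2 (adjusted p = 0.493). The endoplasmic reticulum unfolded protein response was at 0.06 (adjusted p = 0.668; 0.00996 to 0.10 without 1 array), and 1 of its 18 members, the co-chaperone Dnajb9, fell by 0.60 (SE 0.151) when adjusted over the list alone. p53 target genes fell by 0.14 (camera adjusted p = 0.0278, adjusted p = 0.235 with an estimated correlation) with a median of -0.03. Adjusted over the list alone 2 of 18 fell, the antiproliferative Btg2 at -0.77 (SE 0.203) and Trp53inp1 at -0.73 (SE 0.208). The call was lost without wild type 1 (-0.091, adjusted p = 0.114) or wild type 2 (adjusted p = 0.0541) and with array weights (-0.096). The difference was -0.090 without heterozygous 5 and -0.22 with macrophage markers or other-cell markers as covariate.

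Cytokine signalling and proliferation lists did not pass over all 10 arrays without a covariate. IL-7 and STAT5 induced genes were at 0.12 (camera adjusted p = 0.538), with the feedback inhibitor Cish at 0.64 (SE 0.264) and Bcl2l2 at 0.30. IL-7 receptor pathway components were at -0.05 (adjusted p = 0.262; Stat5b -0.22, Ptpn6 -0.31). DNA replication and G1/S genes were at 0.01 (adjusted p = 0.693; Gins2 0.34, Tyms 0.30), where camera ranked the list downwards although the mean was above 0. Camera compares a list with the other genes, and the median difference over all genes was 0.058. The mean of DNA replication and G1/S genes was below 0 in 6 of the 10 fits without 1 array (-0.11 without wild type 1 to 0.12 without heterozygous 2). The list was called higher with macrophage markers (0.18, adjusted p = 0.00176) or other-cell markers (0.19, adjusted p = 0.00232) as covariate. These calls use the preset correlation. Camera with an estimated correlation, over all 10 arrays without a covariate, gave an adjusted p of 0.920. G2/M and mitosis genes were at -0.15 (adjusted p = 0.175, or 0.798 with an estimated correlation; Nusap1 -0.45, Aurka 0.26) and were called without wild type 1 (-0.22, adjusted p = 0.0483) or heterozygous 1 (-0.25, adjusted p = 0.0344), but were at -0.067 without wild type 4 and -0.035 with macrophage markers as covariate. Interferon response genes were at 0.12 (adjusted p = 0.659; Bst2 0.72, Ddx58 -0.36) and immediate early genes at 0.09 (adjusted p = 0.659; Nr4a1 0.47, Ier3 0.71), the latter and cytosolic ribosomal proteins again with camera downwards against means above 0. Immediate early genes were below 0 without wild type 3, wild type 4 or heterozygous 2 (lowest -0.038) and called lower with macrophage markers as covariate (-0.16, adjusted p = 0.00348). With an estimated correlation and no covariate their camera adjusted p was 0.904 over all 10 arrays. Without 1 array, interferon response genes ran from 0.038 to 0.20, IL-7 and STAT5 induced genes from 0.084 to 0.19, IL-7 receptor components from -0.072 to -0.018, Tyms from 0.19 to 0.37, Ptpn6 from -0.39 to -0.20 and Ier3 from 0.42 to 0.90. None of these 6 lists had a member past the test adjusted over the list alone.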

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

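The count of macrophage markers and the test of Hspa9 with a covariate were chosen after the values were seen. Of 92 groups of 5 values examined, 7 had 1 array far from the other 4, where 4.6 would be flagged by chance. All 7 values come from wild type 1 or heterozygous 2. In heterozygous 2 the list mean was 9.44 for monocyte and macrophage genes (next 7.25), 7.49 for neutrophil genes (next 5.96), 8.06 for immediate early genes (next 7.46) and 8.66 for DNA replication and G1/S genes (next 9.13). In wild type 1 it was 7.46 for megakaryocyte genes (next 5.63), 8.49 for the integrated stress response (next 7.92) and 10.35 for B lineage genes (next 10.57).

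Wild type 1 and heterozygous 2 had the highest macrophage marker means, 8.98 and 9.44, 1 array in each genotype. In some other lists too they stood apart together from the other 8 arrays. They were highest for neutrophil (6.73 and 7.49), megakaryocyte (7.46 and 7.62) and immediate early genes (8.10 and 8.06). For DNA replication and G1/S genes they were lowest (8.62 and 8.66). The 2 arrays correlated at 0.982, higher than either did with any other array. An exception was the integrated stress response, where heterozygous 2, at 8.11, lay inside the range of its genotype (7.95 to 8.27). RNA of macrophage-like cells in the sorted samples is a candidate source that was not decided, and the B220 gate should remove such cells. Of 16 measured macrophage markers, 15 were higher in both arrays than in any of the other 8, which describes the pattern and does not test it, because the arrays were picked on the mean of this list. No biological explanation was tested, because both genotypes hold such an array. A difference between culture or sort batches stays open, since the labels give none.

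Hspa9 was examined against the same covariate. With the macrophage marker mean in the model its difference was -0.57 (SE 0.133, 95% interval -0.86 to -0.28). A linear effect of these markers thus did not account for all of it. Wild type 3, 4 and 5, at macrophage means of 5.88, 5.73 and 5.85, lay below every heterozygous array (lowest 6.99). The fit therefore extrapolates between genotypes, and RNA of such cells as a source of the lower Hspa9 level stays undecided. Probe sets without a single gene symbol were tested apart: 0 of 7915 passed in limma, and 722 had an unadjusted p under 0.05.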

How the results depend on the processing

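Macrophage markers as a covariate and leaving out wild type 1 with heterozygous 2 were chosen after seeing the data, and the cause of a change was not tested unless named. Hspa9 stayed lower under every alternative run, from -0.84 to -0.57, and passed over all genes only with array weights (-0.79, adjusted p = 0.0381; range of adjusted p 0.0381 to 0.655). Genes past the threshold were 0, except 137 with array weights (74 higher, 63 lower), 26 without the pair of macrophage-high arrays (8 higher, 18 lower), 2 at an adjusted p under 0.1, and 0 to 22 without 1 array (22 without wild type 1, 3 without heterozygous 2). Lists called were 11, against 0 with an estimated correlation, 5 with fry and 0 with exact permutation, whose tests allow for correlated members or do not compare with other genes, and 9 to 15 under the other alternatives. The 11 called lists kept their direction in all 285 alternative values, and 59 of these missed the threshold. An estimated correlation and exact permutation ended all 11 calls at means that these tests leave as they were: immature and mature B cell -0.67, small pre-B differentiation -0.42, glycolysis 0.34 and T cell and NK cell 0.50, each of which held in the other 24 of 26 alternatives, and cholesterol synthesis 0.19. For the rest, B lineage -0.32, plasmacytoid dendritic cell 1.12, V(D)J recombination -0.17, neutrophil 0.53, p53 targets -0.14 and pre-BCR and BCR signalling -0.14, fry ended the call too. For 4 of the 11 lists exact permutation gave its smallest possible p, 0.0079. Their missed threshold there (adjusted p = 0.0675) reflects the resolution of that test. Cholesterol synthesis also missed with trended variance (0.19), array weights (0.18), other-cell markers (0.154) or macrophage markers (0.152) as covariate. It missed too without the pair of arrays (0.19) and without some single arrays (range 0.16 to 0.21). Neutrophil genes missed above the median row (0.72), with macrophage markers as covariate (0.078) and without some single arrays (0.18 to 0.82). p53 targets missed above the median row (-0.17), with array weights (-0.096) and without some single arrays (-0.20 to -0.090). Pre-BCR and BCR signalling held in 11 of 26. It missed above the median row and with trended variance (-0.14 in both), cyclic loess (-0.131), quantile normalization (-0.128) or array weights (-0.088). It missed as well with other-cell markers (-0.114) or macrophage markers (-0.119) as covariate, without the pair of arrays (-0.138) and without some single arrays (-0.17 to -0.11). Of 1917 values of the 84 named genes other than Hspa9, 1865 stayed as reported, 49 newly passed and 3 reversed. Those 3 were Car1 with array weights (-0.029) and Pf4 with other-cell markers (-0.39) or macrophage markers (-0.38) as covariate. Of 590 values of the 23 uncalled lists, 32 reversed and 53 newly passed: 16 of 24 for monocyte and macrophage, 13 of 26 for pro-B and early progenitor, 6 for mitochondrial ribosomal proteins, 5 each for oxidative phosphorylation and the integrated stress response, 4 for stroma and 2 each for G2/M and for DNA replication and G1/S. DNA replication and G1/S genes were at -0.0065 with array medians subtracted, -0.073 with array weights, -0.0022 without the pair of arrays and -0.11 to 0.12 without 1 array. They were called at 0.19 with other-cell markers and 0.18 with macrophage markers as covariate. With other-cell markers and with macrophage markers as covariate, in that order, the cytosolic heat shock response was at 0.025 and 0.024 (-0.085 to 0.021 without 1 array), genes next to Hspa9 at 0.011 and 0.0074, interferon response at -0.010 and -0.0035, iron-sulfur genes at -0.049 and -0.051 (-0.0065 to 0.11 without 1 array) and immediate early genes at -0.162 and -0.165, both then called (-0.038 to 0.26 without 1 array). Megakaryocyte genes were at -0.18 with macrophage markers as covariate. Cytosolic ribosomal proteins were at -0.0020 with array weights and -0.013 to 0.029 without 1 array, plasma cell genes at -0.0056 with quantile normalization and -0.0057 with array weights, erythroid genes at -0.011 with quantile normalization, and the endoplasmic reticulum unfolded protein response at -0.017 without the pair of arrays. Replicate numbers did not clearly pair the samples: deviations of same-numbered arrays correlated at -0.53, 0.21, 0.53, 0.04 and 0.31. No heterozygous array matched the wild type array of its own number best. The labels call the wild type mice littermates, and replicate 1 was the only male in each genotype, so a pairing is not excluded. With the replicate number as a block 0 genes passed and 14 lists were called. Newly called there were monocyte and macrophage (adjusted p = 0.00436), pro-B and early progenitor (0.0327) and stroma genes (0.0357). Dim probe sets limit low genes, since the filter leaves out 4985.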

Other observations

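Without wild type 1 and heterozygous 2, a comparison chosen after seeing the data, 26 genes passed the limma threshold over all genes. The 18 lower ones included the B cell surface receptors Cd22 (-1.08, adjusted p = 0.0203), Fcgr2b (adjusted p = 0.0286) and Btla (-0.98, adjusted p = 0.0356), the activation marker Cd69 (-1.10), Cd55 (-2.09), Bank1 (-1.59) and the transcription factor Bhlhe41 (-1.57). The 8 higher ones included Nol4l (0.86), Adgrg1 (1.30), the Notch target Heyl (1.92) and asparagine synthetase Asns (1.08, adjusted p = 0.0400). These genes were named after their values were seen. Of the 35 splits of those 8 arrays 2 gave as many genes, the real one with 26 and another with 1931, so chance cannot be excluded. The larger count was for wild type 2 with heterozygous 3, 4 and 5 against the other 4. That is the genotype split with wild type 2 and heterozygous 1 exchanged. It follows the first principal component of all 10 arrays, where the groups lie at 4.4 and below and at 10.9 and above. This points to a structure of the samples that genotype alone does not explain.

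Other splits of all 10 arrays bear on the counts of the report, the first of them chosen after its count was seen. For the genes past the threshold the real count was 0 (highest other 0), so all 100 splits reached it and nothing follows for that count. Of the 100 splits, the real one included, 13 gave as many genes at an unadjusted p under 0.05 (1650, highest other 3668) and 20 gave as many camera calls (11, highest other 17). Of the splits with as many camera calls 16 put wild type 1 and heterozygous 2 in one group. Among the 54 that part these arrays, as the real one does, 4 gave as many camera calls (highest other 13) and 6 as many genes at an unadjusted p under 0.05 (highest other 2901), a restriction chosen after the counts were seen. Apart from the real one, those 4 each exchange a single pair of arrays between the genotypes, so they keep most of the genotype contrast. Chance is not excluded for the counts of camera calls and of genes at an unadjusted p under 0.05, with or without that restriction.

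The tests in the rest of this part, except the permutation test of ribosome biogenesis genes without a covariate, were chosen after the values were seen. The lower immature and mature B cell genes may reflect fewer cells at that stage in heterozygous colonies, a hypothesis from these same data. More macrophage RNA in the heterozygous arrays would let the difference vanish with the macrophage covariate, and it was -0.72 (SE 0.207, 95% interval -1.21 to -0.23). For wild type 3, 4 and 5, whose macrophage means lay below every heterozygous array, that fit extrapolates. Wild type 1 and 2 lay within the heterozygous macrophage range. Their immature and mature B cell means, 8.47 and 9.32, were above every heterozygous array (highest 8.17). A lower share of B-lineage cells of every stage would lower pro-B genes as much, and the difference between both list means was -0.92 between genotypes (exact permutation p = 0.0079, the smallest possible). That test cannot exclude a lower share. The pro-B list also holds early progenitor genes, and its higher mean was known beforehand. The B lineage list itself fell by 0.32, with 12 of 14 members below 0. Sex of the mice would leave no difference among the 8 females (sex read from Y-linked genes and Xist, 1 male per genotype), where it was -0.71 (exact permutation p = 0.0286, the smallest possible). That p was fixed beforehand, because every heterozygous array already lay below every wild type array. With 1 male in each genotype, sex was also balanced, so the p adds no test of it. A lower share of B-lineage cells, batch of culture or sort, and a change within cells in place of a change of stage stay open.

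The integrated stress response list was at 0.35 over the 8 arrays (exact permutation p = 0.0286, camera adjusted p = 0.000108, adjusted p = 0.493 with an estimated correlation), against 0.21 over all 10. A higher ATF4 response in heterozygous cells may account for it but was not tested by these values, which restate the pattern and rest on leaving out wild type 1, the array with the highest list mean of all 10 (8.49). More macrophage RNA cannot be told apart from it either: with the macrophage covariate the difference over the 8 arrays was 0.25 (SE 0.123), and its 95% interval from -0.07 to 0.57 holds both 0 and the full difference. Over all 10 arrays the same covariate lowered the list difference from 0.21 to 0.084 (camera adjusted p = 0.901).

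With the macrophage covariate the transcription factor Myc was at 0.75 (adjusted p = 0.0752) and the nucleolar Gar1 at 0.69 (adjusted p = 0.0653), neither past the threshold, and without it at 0.34 (adjusted p = 0.697) and 0.37 (adjusted p = 0.592). Both were picked after their values were seen. A MYC-driven rise of ribosome biogenesis genes was tested with a list drawn up once these values were known. The prediction, a rise at p under 0.05 without the covariate, failed: over 21 measured genes the difference was 0.033 (exact permutation p = 0.881), from 8.86 ± 0.465 to 8.90 ± 0.278 (SD), with 12 of 21 above 0 and 0 at an unadjusted p under 0.05. It was -0.040 without wild type 1 and heterozygous 2, and 0.26 (95% interval 0.0015 to 0.52) with the macrophage covariate. The values gave no rise outside the covariate model, but a p that misses the threshold at this spread does not exclude one, so the explanation stays open.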
